A study of Mus musculus with 2 samples.

How the data were processed

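MEFs were profiled by MeRIP-seq. Per the labels' protocols, RNA was extracted with TRIzol, poly(A) RNA was isolated and precipitated with an m6A antibody, and the eluted RNA was reverse transcribed, amplified, tagmented and indexed by a Smart-Seq2 procedure. The protocols in the labels name no fragmentation of the RNA before precipitation. There were 2 libraries, 1 MEF input and 1 MEF m6A IP. Per the submitters' processing notes, Trimmomatic, Bowtie2 and MACS2 were used with genome build mm10, and their versions and options are not given in the sources used here. Those notes do not say in which role each tool was used. The IP library's peak list was analysed, and read files and coverage of either library were not used here.

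The list follows the narrowPeak layout that MACS2 writes, with several summits per region, and has no header. Its fold value is the ratio of IP to background at the summit, as the authors' peak caller deposited it. The deposited −log10 p and −log10 q values are those of the same summit, and the deposited score was within 1 unit of 10 times −log10 q at 100% of summits. The other deposited value is the distance of the summit from the start of its region. All were used to describe and rank peaks within this list only. Peaks came from 1 IP library, so no peak could be checked in a replicate. Total reads per library are not stated in the labels.

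Depth was recovered from the list. MACS2's fold is the scaled IP reads plus 1 over the background plus 1, and its p-value is a Poisson tail with that background as the mean. Solving both together for each summit gave a whole number of IP reads and a background. With IP reads scaled by 0.815 (1.23 IP reads per background library read), 98.2% of summits gave a background that was a whole read number at the summit (62.8%; tolerance 0.02), the mean of a 1-kb window (18.4%; tolerance 0.005), the mean of a 10-kb window (0.940%; tolerance 0.0005) or the genome-wide value of 22.1 reads (16.2%). With the scale 1% off, 31.7% passed the same limits. The fit needed a second, unscaled library as the control, which the labels do not name as the input. Reads were counted as extended to 80 nt, the minimum region width. On 3256 simulated summits, 97.9% were recovered exactly. The remaining 1.77% of real summits have a background without a whole-number match and no interval.

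Genes came from a RefSeq gene table of GRCm38.p6, the same assembly as mm10, with 49943 placed genes, their spans and biotypes. A summit was assigned to each gene whose span contains it. The plan, made before the data were examined together with the gene lists, the rule for named genes and the processing alternatives, had used exons. No exon table or genome sequence was used here, so the planned shares near stop codons, in gene parts and in long internal exons and the planned motif count were not run. Fold by gene part was replaced by fold by kind of gene, and lists were matched on the length of the gene span in place of exonic length. Of 483 list entries, 483 matched a gene symbol, since 0 were unmatched and 0 needed a synonym.

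Each of 19 fixed lists was given as members with a summit with an exact 95% binomial interval, and as a percentile among 10000 random lists matched on biotype and on 10 equal-sized classes of gene span length. Ties counted equally to either side. The percentiles describe this library and are not p-values. Expression was not used for matching, because no expression values were used here. On 200 simulated lists of 30 genes, 1.50% without an effect, 37.5% with odds raised by 2 and 97.5% with odds raised by 4 passed the 97.5th percentile. The median strongest fold of members was set against random lists of genes with a summit, for lists with at least 3 protein-coding members holding one. Shares of summits have Wilson intervals. Ratios of reads have exact intervals, from the Poisson distribution where the background was the genome-wide value, taken as fixed, and from the binomial otherwise.

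Named genes were every member of the m6A machinery list with Pou4f2 and Isl1, up to 3 members of each other list by strongest fold, the 10 protein-coding genes with the highest fold and the 5 with the most summits. Members named in the report as being without a summit, and Fos, Jun, Egr1, Atf3, Myc and Sparc, were chosen after their values were seen. Some genes that the rule covers are not reported here. The genes named among the additional observations beyond the rule were chosen in the same way. A further 5 marker lists, for macrophages, lymphocytes, neutrophils and mast cells, germ cells and hepatocytes, were written after the depth of Lyz2 had been seen and before their own values were examined.

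Alternatives were a −log10 q of at least 5, a fold of at least 5, 1 summit per region, region midpoints, leaving out summits in several protein-coding genes together with genes that share a symbol with a pseudogene marked -ps (339 genes), any overlap or 50% overlap of the region with a gene, and random lists without length matching. Leaving out the 339 genes takes away all of their summits by definition. Added after seeing the data were the limit to summits with a measured background and the matching of fold on background reads. A measured background was any but the genome-wide value, so means of 1-kb and 10-kb windows counted as measured. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.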

Results

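The data describe N6-methyladenosine (m6A), a methyl mark on adenosines of messenger RNA, in mouse embryonic fibroblasts (MEFs), connective tissue cells cultured from embryos that are widely used as starting cells for reprogramming into neurons. Poly(A) RNA was precipitated with an antibody against m6A and sequenced (MeRIP-seq), and an input library was made from the same kind of cells. The labels gave 2 groups, MEF input and MEF m6A IP, with 1 library each, so no value has a replicate and no p-value is given across genes or summits. The series as a whole asks how m6A bears on axon formation and on reprogramming toward retinal ganglion cells. The labels do not say whether these cells carried the reprogramming factors, and the comparison available was IP against background. The values are those of the authors' peak list: each summit has a fold of IP over background and a q-value.

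The peak list held 47639 summits in 24141 called regions of the mm10 genome. A single summit was found in 59.1% of the regions, and the most in any region was 22. Regions had a median width of 190 nt (quartiles 136 and 290, range 80 to 4447). The median fold was 2.12 (quartiles 1.75 and 2.74, range 1.05 to 49.2), 57.0% of summits reached a fold of 2, and 1733 (3.64%) reached a fold of 5. The smallest −log10 q in the list was 1.3, which corresponds to a q of 0.05. The read numbers behind each summit were recovered from the fold and the p-value together. IP reads over a summit had a median of 170 (quartiles 99 and 328, range 51 to 168571), and background reads a median of 59.6 with a maximum of 55243.6. Intervals on ratios of these reads are exact 95% intervals without the peak caller's pseudocount, and they cover counting error only, since PCR reads without molecular identifiers are not independent molecules. For a gene's strongest summit they do not allow for its choice as the highest of several, which favours genes with many summits.

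Summits lay almost entirely within genes. Protein-coding gene spans held 46669 of them, or 98% (Wilson 95% interval 97.8 to 98.1). Outside these spans, 410 lay in pseudogenes (0.861%), 209 in long noncoding RNA genes (0.439%), 26 in other genes and 325 in no annotated gene (0.682%). A summit in several kinds of gene was counted once, in the order protein-coding, long noncoding RNA, other gene, pseudogene. The median fold was 2.11 in protein-coding genes (95% interval of the median 2.10 to 2.12), 2.19 in pseudogenes (2.11 to 2.28), 2.19 in long noncoding RNA genes (2.06 to 2.31), 2.55 in the 26 summits of other genes (2.12 to 2.93) and 2.31 outside genes (2.17 to 2.44). The intervals on shares and medians treat summits as independent, although many share a region or gene, so they can be too narrow. Of 21887 annotated protein-coding genes, 5944 (27.2%) held a summit. The median such gene had 3 called regions, 1339 genes (22.5%) had 1, and 465 had 10 or more. Among the autosomes the share of protein-coding genes with a summit ran from 19.2% on chromosome 7 to 33.7% on chromosome 18. It was 19.8% on X, and 3 of 256 genes on Y held a summit. Gene assignment used gene spans, so exon, intron and UTR positions are not given, and 1710 summits (3.59%) lay in more than 1 protein-coding gene.

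The 10 protein-coding genes with the highest folds reached 22.6 to 49.2. The highest fold, 49.2, was at position 66224898 of chromosome 3, inside Ptx3, which encodes the secreted pattern recognition protein pentraxin 3, and also inside the longer Veph1 (1396 IP reads, ratio interval 48.8 to 54.2). Ppp2ca, the catalytic subunit of protein phosphatase 2A on chromosome 11 from 52098824 to 52122749, reached 39.9 at position 52122061 (1131 IP reads, 39.3 to 44.2). Pkd2, encoding the cation channel polycystin 2, reached 32.3 on chromosome 5 (31.5 to 35.9). Jund, a subunit of the AP-1 transcription factor, reached 32.2 on chromosome 8 from 948 IP reads over 23 background reads (22.3 to 53.3). The list went on with Timp2, an inhibitor of matrix metalloproteinases, at 27.9, the RNA-binding protein gene Ybx1 at 27.4, the sulfotransferase gene Sult1a1 at 24.6, the sphingosine-1-phosphate phosphatase gene Sgpp1 at 23.4 and Cdkn1c, which encodes a cyclin-dependent kinase inhibitor, at 22.6. Cdkn1c had the most reads of these at its strongest summit, with 4044 over a background of 145 (19.3 to 27.0).

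For the strongest summits of Ptx3, Ppp2ca, Pkd2, Ybx1 and Sult1a1 the background was the genome-wide value of 22.1 reads, which the peak caller substitutes where the local background is lower, so their folds are lower bounds of the local ratio. Intervals at that background take it as fixed and leave out its counting error. They can therefore look more precise than intervals at a measured background, and their upper limits do not bound the local ratio. The same holds for genes named below with that background, among them Ythdf2, Klf9, Lrp6, Socs1 and Ccne1. Of the 10 summits with the highest fold, 7 had that background, as had 431 of the top 1000. Counting only summits with a measured background, an alternative chosen after seeing the data, the strongest fold was 34.5 in Ppp2ca, 20.8 in Ptx3, 20.2 in Ybx1 and 10.3 in Pkd2. It stayed at 32.2 in Jund, 27.9 in Timp2, 23.4 in Sgpp1 and 22.6 in Cdkn1c. The measured backgrounds of Jund, 23 reads, and Sgpp1, a 1-kb mean of 23.6, were close to the genome-wide value. In Jund 6 of 7 summits and in Sgpp1 10 of 15 had the genome-wide background. Sult1a1 had 1 summit, at the genome-wide background, and so no value under that setting. Leaving out summits in overlapping protein-coding genes together with multi-copy genes left no summit in Ptx3, Veph1 or Ybx1, as that setting removes such summits by definition.

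**Figure D1:**
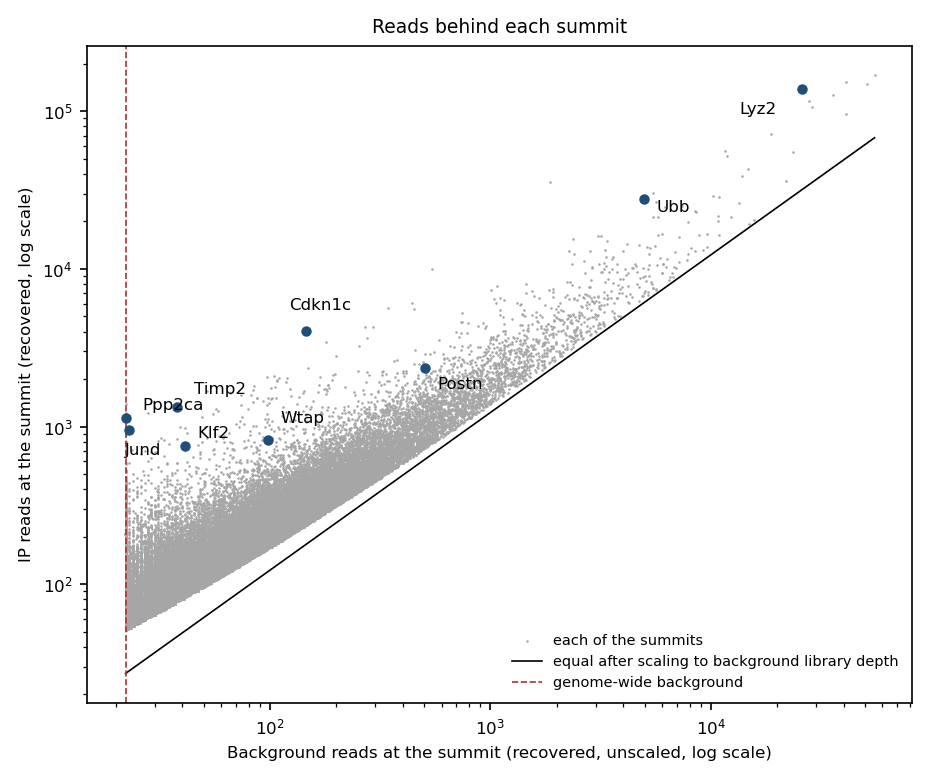
IP reads against background reads at each summit, both recovered from the deposited fold and p-value, on log axes; named points are the strongest summit of a gene, the solid line marks equality after scaling to the depth of the background library and the dashed line the genome-wide background of 22.1 reads. Ppp2ca and Jund sit at or near the dashed line with 1131 and 948 IP reads, and Lyz2 lies at the deep end with 137286.

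Some genes held 49 or more summits within their span, among them Thbs2, Eprs, Cenpp and Jak1. Thbs2, encoding the matricellular protein thrombospondin 2, held 56 summits in 23 regions with a strongest fold of 2.48 (2.30 to 2.68). Eprs, the glutamyl-prolyl-tRNA synthetase gene, held 53 in 29 regions with a strongest fold of 8.43 (7.48 to 10). Jak1, encoding a tyrosine kinase of cytokine receptors, held 49 summits in 24 regions with a strongest fold of 6.56 (4.94 to 9.21). Cenpp, a centromere protein gene, also held 49, but its span covers those of the matrix genes Omd and Aspn, and its strongest fold of 8.14 came from a summit shared with Omd. Without overlapping-gene summits and multi-copy genes together, the strongest fold in Cenpp was 3.64.

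**Figure D2:**
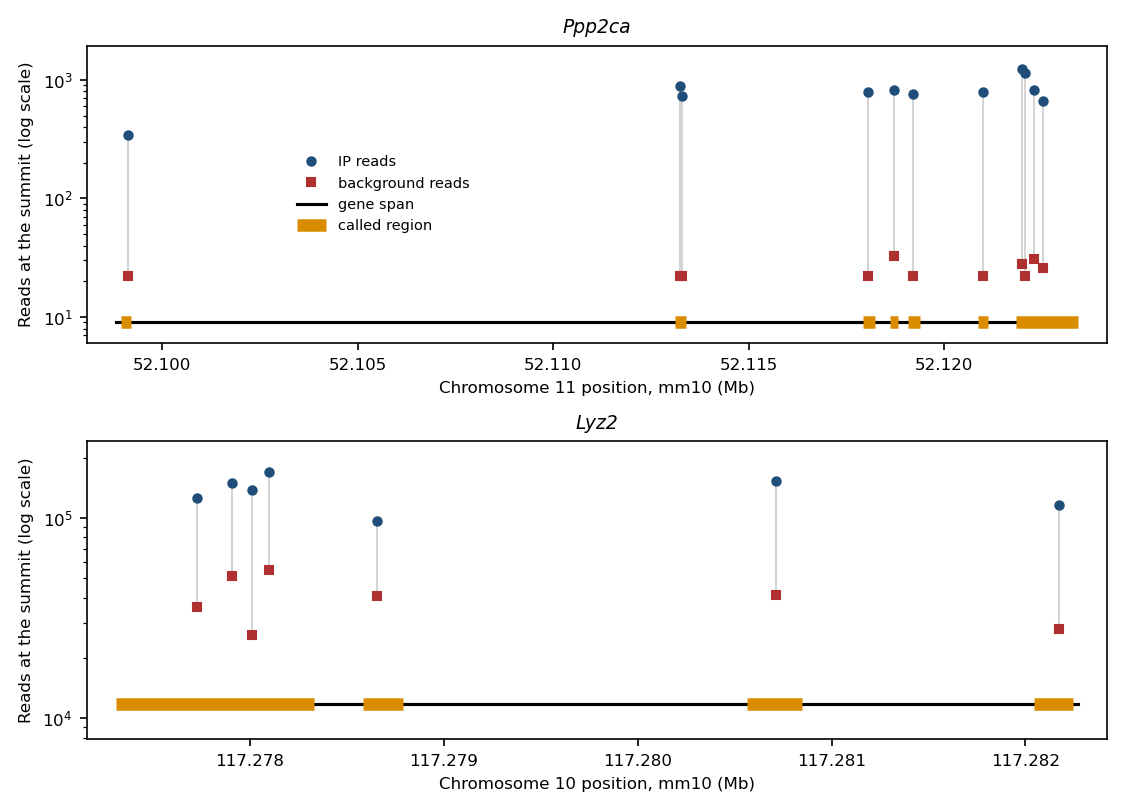
Summits along Ppp2ca (chromosome 11) and Lyz2 (chromosome 10) in mm10 coordinates; circles are IP reads and squares background reads at each summit on a log axis, with the gene span and called regions drawn along the bottom. Ppp2ca has 341 to 1225 IP reads at its summits over backgrounds of 22.1 to 33, and Lyz2 has 96633 to 168571 IP reads over backgrounds of 25925 to 55244.

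Whether transcripts of the m6A machinery themselves carried m6A enrichment was examined first. Of the 22 genes for writers, erasers and readers of m6A, 12 held a summit (54.5%, exact interval 32.2 to 75.6), against a median of 7 in random lists of the same gene lengths, which placed the list at the 98.2nd percentile. Highest were Hnrnpc, encoding an RNA-binding protein whose access depends on m6A-altered RNA structure, at 7.5 (6.78 to 8.85), and Wtap, encoding the adaptor of the writer complex, at 6.82 (6.29 to 7.52; 823 IP reads at position 12975125 of chromosome 17). The readers followed with Ythdf2 at 4.77 (4.14 to 5.85), Hnrnpa2b1 at 4.64 (4.31 to 5.05), Fmr1 at 4.08 (2.68 to 6.91), Ythdc1 at 3.5 (2.93 to 4.40), Ythdf3 at 3.0 (2.47 to 3.83), Ythdf1 at 2.58 (2.08 to 3.34) and Igf2bp3 at 2.27 (1.77 to 3.01). The eraser gene Alkbh5 reached 2.58 (2.08 to 3.34), and the writer genes Rbm15 and Mettl16 reached 2.97 (1.96 to 4.89) and 2.25 (1.41 to 3.88). The background was a 10-kb mean for Hnrnpc and a 1-kb mean for Wtap, Hnrnpa2b1 and Igf2bp3. Their intervals count background reads of the whole window, not those at the summit. For Fmr1, Rbm15 and Mettl16 the background was counted at the summit, so this order does not compare like backgrounds. The strongest summit of Ythdf2 had the genome-wide background. On measured backgrounds its strongest fold was 3.48, below those of Hnrnpa2b1 and Fmr1, which stayed at 4.64 and 4.08.

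Neither gene of the catalytic writer pair, Mettl3 and Mettl14, held a summit. Virma, Zc3h13, Rbm15b, Cbll1, the eraser gene Fto and the reader genes Ythdc2, Igf2bp1 and Igf2bp2 had none either. A gene without a summit can be unmethylated, little expressed or below the threshold at this depth, and these are not separable here: with only measured backgrounds Alkbh5, Ythdf1 and Ythdc1 had no summit and the list of 9 remaining members was at the 87.5th percentile. The strongest summits of Rbm15 and Igf2bp3 also lay in Slc16a4 and Malsu1. Without overlapping-gene summits and multi-copy genes together, the strongest fold in Rbm15 was 1.61, Igf2bp3 had no summit and the list stood at the 97.46th percentile, and Mettl16 had no summit at a −log10 q of at least 5.

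Transcription factors that drive neuronal fate were nearly without summits. Among 20 factors of neuronal reprogramming and retinal ganglion cell identity, 1 held a summit (5.00%, 0.127 to 24.9), against a random median of 5, at the 1.51st percentile. Pou4f2 (also called Brn3b) and Isl1, factors of retinal ganglion cell development, had none. The exception was Sox4, an SRY-box factor also active in mesenchyme, with 9 summits and a strongest fold of 2.35 (1.80 to 3.14). Limited to a −log10 q of at least 5, the list moved to the 2.96th percentile, and without overlapping-gene summits and multi-copy genes together to the 2.71st.

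Genes that restrain the conversion of fibroblasts to neurons held summits more often than most random lists. Of 14 such genes, 8 held a summit (57.1%, 28.9 to 82.3; random median 4), at the 98.4th percentile. Chaf1a, a histone chaperone subunit of chromatin assembly factor 1, reached 3.71 (3.13 to 4.64). Rest, encoding the repressor of neuronal genes in non-neuronal cells, reached 3.27 (2.27 to 5.04), and Id1, an inhibitor of basic helix-loop-helix factors, reached 2.97 (2.54 to 3.5). Ptbp1 and Ptbp2, splicing regulators that were members of the list, had no summit. The strongest summit of Chaf1a also lay in Ubxn6 and was at the genome-wide background. Its strongest fold was 2.94 on measured backgrounds and 2.81 without overlapping-gene summits and multi-copy genes together. The list stood at the 96.9th percentile without overlapping-gene summits and multi-copy genes together and at the 97.46th with a −log10 q of at least 5.

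Axonogenesis and axon guidance genes held summits about as often as random lists. Of 44 genes, 12 had a summit (27.3%, 15.0 to 42.8; random median 13), at the 43.0th percentile. Sema3c, encoding a secreted guidance cue, held 48 summits in 18 regions and reached 6.77 (4.65 to 10.9). Klf9, a transcription factor that limits axon growth, reached 6.0 (5.32 to 7.24), and Nrp1, the semaphorin and VEGF co-receptor, held 37 summits and reached 4.02 (3.48 to 4.80). Dcx, Tubb3, Map2, Mapt, Stmn2, Robo1 and Dcc had no summit. Klf9 had the genome-wide background at each of its 10 summits, and no summit remained with measured backgrounds.

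Fibroblast and extracellular matrix genes held summits at low fold. Of 34 genes, 15 had a summit (44.1%, 27.2 to 62.1; random median 10), at the 96.8th percentile, within the middle 95% of random lists. It was at the 99.15th percentile with a −log10 q of at least 5 and at the 98.4th without length matching, but at the 17.4th with a fold of at least 5, where 0 members remained, and at the 96.725th to 97.045th under the other alternatives. The highest were Fbn1, encoding the microfibril protein fibrillin 1, at 4.43 (3.01 to 7.15), Postn, encoding the matricellular protein periostin, at 3.78 (3.61 to 3.97) with 35 summits, and Snai2, a mesenchymal transcription factor, at 3.72 (3.06 to 4.61). Across the members with a summit, the median strongest fold was 2.10, at the 0.31st percentile of random lists of genes with a summit and equal length, and at the 0.30th when these were matched on background reads. Col1a1, Col1a2, Col3a1, Fn1 and Vim, among the best known products of fibroblasts, had no summit. The macrophage gene Lyz2 had the deepest background of any gene in the same list of peaks, 55243.6 reads. The highest among the 15 fibroblast genes with a summit was 9572.89, in Sparc. Background was recovered only at summits, so the fibroblast genes without one have no value to compare.

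Early response transcription factors stood highest of all fixed lists. Of 17 genes, 11 held a summit (64.7%, 38.3 to 85.8; random median 4), at the 99.99th percentile. Jund led with 32.2 and was followed by Klf2, a Krüppel-like factor induced by shear stress, at 14.6 (10.9 to 21). Junb, another AP-1 subunit, reached 3.49 (3.21 to 3.82). The strongest folds of the other 8 members, which included Fos, Jun, Egr1, Atf3 and Myc, ran from 1.79 in Fos to 2.92 in Atf3. Fosb, Fosl1, Fosl2, Egr3, Ier3 and Maff had no summit. With a fold of at least 5, 2 of the 17 genes held a summit, at the 97.2nd percentile.

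Chromatin regulators lay at the other end. Of 30 genes, 3 held a summit (10%, 2.11 to 26.5; random median 9), at the 0.755th percentile. Eed, a core subunit of the Polycomb repressive complex 2, held 14 summits and reached 4.40 (2.99 to 7.10). The histone demethylase genes Kdm5b and Kdm6a reached 2.16 (1.69 to 2.85) and 1.78 (1.14 to 2.93), and Kdm6a had no summit at a −log10 q of at least 5. The genes Ep300, Crebbp, Kmt2a, Kmt2d and Arid1a had no summit.

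Signalling and cell cycle genes resembled random lists. Of 36 components of the Notch, TGF-beta, BMP, Wnt, Hippo, Hedgehog and cytokine pathways, 11 held a summit (30.6%, 16.3 to 48.1), at the 61.7th percentile. Lrp6, a Wnt co-receptor gene, reached 5.86 (5.19 to 7.08), Socs1, a feedback inhibitor of cytokine signalling, 4.55 (3.93 to 5.61) and the Wnt receptor gene Fzd2 3.71 (2.55 to 5.85). With measured backgrounds alone the strongest fold in Lrp6 was 2.84 and Socs1 had no summit. Of 24 cell cycle genes, 9 held a summit (37.5%, 18.8 to 59.4), at the 78.1st percentile. Ccne1, encoding the G1/S cyclin E1, reached 4.80 (4.17 to 5.89), Rb1, the retinoblastoma tumour suppressor gene, 3.99 (2.79 to 6.12) at a summit shared with Lpar6, and Pcna, the DNA polymerase clamp gene, 3.09 (2.52 to 3.85). Neither Rb1 nor Pcna had a summit left without overlapping-gene summits and multi-copy genes together, a setting that removes such summits by definition.

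Among genes for abundant transcripts, ribosomal protein genes rarely held a summit, and those of oxidative phosphorylation and housekeeping functions often did. Of 38 ribosomal protein genes, 2 held a summit (5.26%, 0.644 to 17.7; random median 8), at the 0.235th percentile, and Rpl5 reached 2.04 (1.68 to 2.52). Of 26 genes of oxidative phosphorylation, 12 held a summit (46.2%, 26.6 to 66.6; random median 7), at the 98.4th percentile. The electron carrier gene Cycs reached 3.82 (3.16 to 4.70), and the complex III genes Uqcrb and Uqcrc1 reached 3.54 (3.0 to 4.25) and 3.08 (2.80 to 3.43). Of 18 other abundant housekeeping genes, 9 held a summit (50%, 26.0 to 74.0; random median 4), at the 98.9th percentile. The glycolytic genes Eno1 and Pgk1 reached 3.39 (2.95 to 3.94) and 2.47 (2.03 to 3.04), and B2m, the light chain of MHC class I, reached 2.47 (2.38 to 2.57), at a summit shared with Patl2. The median strongest fold of the housekeeping members, 1.90, was at the 0.48th percentile, and Actb, Gapdh and Eef1a1 had no summit.

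Many of these genes have processed pseudogenes, whose sequence can take up or lend reads. Without overlapping-gene summits and multi-copy genes together, Cycs, Pgk1 and B2m had no summit left. The ribosomal list had 0 members with a summit left, at the 0.02nd percentile. The oxidative phosphorylation list was at the 98.2nd percentile and the housekeeping list fell to the 87.8th. That setting takes away all summits of multi-copy genes by definition. These losses therefore do not measure reads shared with pseudogenes. Of 10 nuclear and imprinted long noncoding RNAs, 2 held a summit, at the 98.3rd percentile of lists drawn from all long noncoding RNA genes (median 0). Malat1, a nuclear speckle RNA, reached 2.80 (2.74 to 2.86) from 10711 IP reads, and H19, an imprinted fetal RNA, reached 1.94 (1.77 to 2.13). Neat1, Meg3, Xist and Kcnq1ot1 had none.

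**Figure D3:**
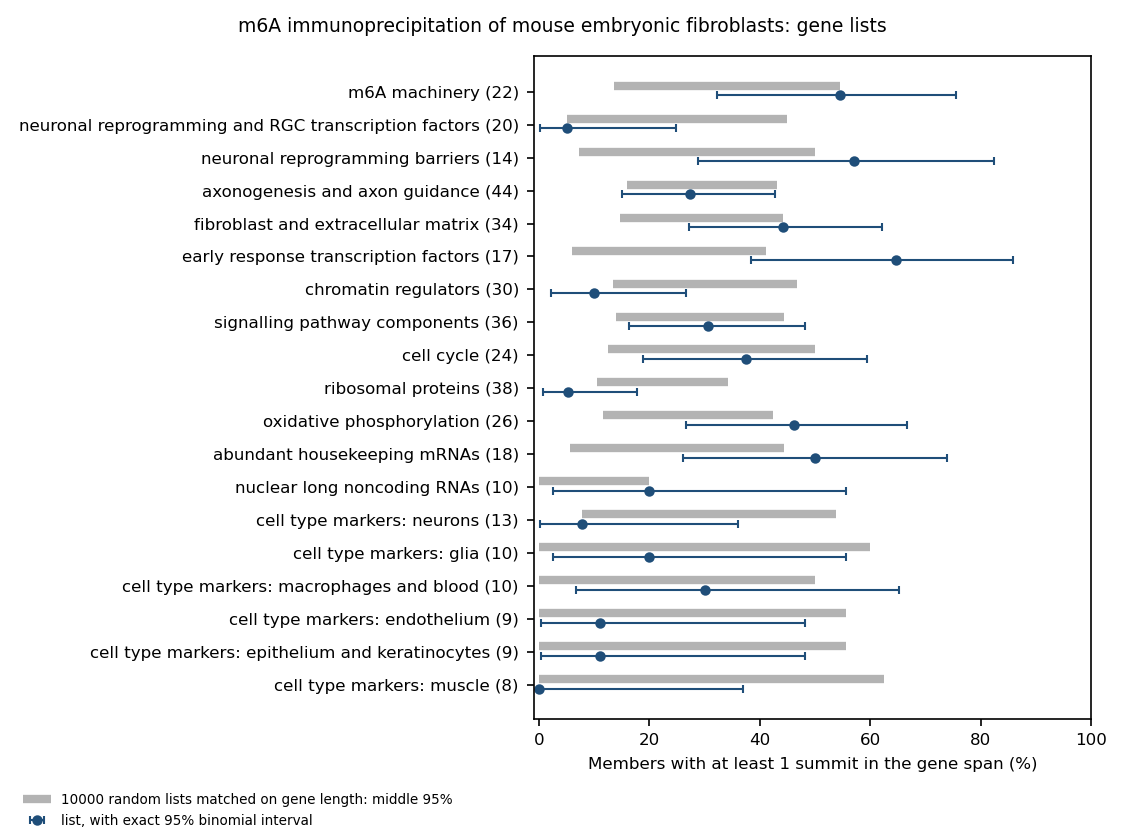
Percentage of members with at least 1 summit for the 19 fixed gene lists, with list sizes in parentheses; points carry exact 95% binomial intervals and grey bars show the middle 95% of 10000 random lists matched on gene length. Early response transcription factors (64.7%) lie well to the right of their grey bar, and ribosomal proteins (5.26%) and chromatin regulators (10%) lie to the left of theirs.

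Of the 19 lists, 6 were above the 97.5th percentile and 3 below the 2.5th, where 0.95 random lists would fall outside that range. The random lists were not matched on expression, so these counts do not separate methylation from expression of the members. Ties counted equally to either side. The m6A machinery, neuronal factor and nuclear long noncoding RNA lists each equalled a limit of the middle 95% of random counts. With summits of a fold of at least 5 alone, 0 lists were above and 0 below.

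Markers of cell types other than fibroblasts were mostly without summits, with macrophage genes as an exception in depth. Of 10 macrophage and blood markers, 3 held a summit (30%, 6.67 to 65.2), at the 73.2nd percentile. Cd14, a co-receptor for bacterial lipopolysaccharide, reached 4.99 (4.24 to 5.97), and Ptprc, the pan-leukocyte CD45 gene, reached 2.48 (1.98 to 3.22). Lyz2, the lysozyme gene of myeloid cells on chromosome 10 from 117277541 to 117282272, reached 4.32 with 137286 IP reads, for which no interval is given because its background was not resolved to a whole read number. Csf1r, Adgre1, Cd68, Itgam and the haemoglobin genes had no summit. Of 13 neuronal markers 1 held a summit, at the 4.83rd percentile: Rbpms, a retinal ganglion cell marker also expressed outside the nervous system, at 4.59 (3.97 to 5.65). Its 5 summits were all at the genome-wide background, and on measured backgrounds the neuronal list had 0 members with a summit, at the 1.075th percentile.

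Of 10 glial markers, Slc1a3, a glutamate transporter gene, reached 4.05 (2.70 to 6.69) and Gfap, an intermediate filament gene, 3.61 (2.95 to 4.67), which placed the list at the 30.3rd percentile. Tek, an angiopoietin receptor gene, was the only one of 9 endothelial markers with a summit, at 2.62 (2.11 to 3.38; 15.1st percentile), and with measured backgrounds its strongest fold was 1.81. Krt19, a simple epithelial keratin gene, was the only one of 9 epithelial markers, at 3.89 (3.35 to 4.65; 15.6th percentile). Of 8 muscle markers, 0 held a summit (exact upper limit 36.9%), at the 4.40th percentile.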

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

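The alternative limited to measured backgrounds was chosen after seeing the data. With a fold of at least 5, 1733 summits and 593 genes remained, with 0 lists above the 97.5th percentile and 0 below the 2.5th, as that limit leaves few members in any list. Merging to 1 summit per region left 24141 summits by construction. Without overlapping-gene summits and multi-copy genes together, 3 lists were above the 97.5th percentile; which of these removals caused it was not tested. The genes with a summit otherwise numbered from 5209 (−log10 q of at least 5) to 5959 (any overlap of the region), with 5414 on measured backgrounds, within 1.5 times of 5944. Lists above the 97.5th percentile otherwise numbered 5 to 7, not always the same lists, and lists below the 2.5th 2 to 4. The median fold with a −log10 q of at least 5 was 2.51 in long noncoding RNA genes, 2.69 outside genes, 2.37 in protein-coding genes and 2.39 in pseudogenes, since that limit removes low folds. With 1 summit per region, the strongest by construction, it was 2.33 in long noncoding RNA genes, 2.30 in protein-coding genes and 2.37 in pseudogenes. On measured backgrounds it was 2.16 outside genes and 2.02 in protein-coding genes, since the summits left out have higher folds. With region midpoints the median outside genes was 2.19 against 2.31, and each kind of gene stayed within the interval of its main median. Of the named genes' strongest folds, 9 of 66 moved beyond their interval on measured backgrounds, where 7 more genes had no summit left, and 3 without overlapping-gene summits and multi-copy genes, where 11 more had none. Alternatives on transcript choice, order of gene parts, stop codon window, motif window and exon length were not run, since they need exons or sequence not used here. No summit had fewer than 51 IP reads. At the genome-wide background, the lowest one used, 52 IP reads gave a −log10 q of 1.58 in Efnb2. The smallest in the list was 1.3, so the limit lies near where that background meets the q threshold of 0.05. A place with fewer IP reads would therefore have no summit whatever its enrichment. How depth and the peak caller's options each set that background was not tested. No paired analysis was possible because each group has 1 library.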

Other observations

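All tests in this part were chosen only after the result was seen. The deepest background in the list was that of Lyz2, the myeloid lysozyme gene. After Lyz2, with 55243.6 background reads at its deepest summit, came Spp1, encoding the secreted phosphoprotein osteopontin, with 23496.7, the lysosomal protease gene Ctsb with 21807.2, the ferritin light chain gene Ftl1 with 15754.9 and Ptn, encoding the growth factor pleiotrophin, with 12314.9. Matrix genes followed, with Sparc at 9572.89, Postn at 9170.31, the small proteoglycan gene Dcn at 6832.35 and the collagen crosslinking gene Lox at 6749.1, beside the ferritin heavy chain gene Fth1 at 8483 and the polyubiquitin gene Ubb at 7376.61. The median over genes with a summit was 84.0. Within this deep group the strongest fold differed: it was 4.53 (4.39 to 4.67) in Ubb and 4.52 (4.40 to 4.66) in Tmsb4x, encoding the actin-binding peptide thymosin beta 4, against 1.25 (1.22 to 1.29) in Fth1 and 1.15 in Lox.

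Fold fell as background rose. The median was 2.65 over the 7698 summits at the genome-wide background, 2.37 for measured backgrounds of 22 to 50 reads, 1.82 for 100 to 200 and 1.56 for 1000 or more. A summit of low depth passes the q-value only at a higher fold, so the list itself sets part of this order, and no separate test of it was run.

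Genes of macrophages held summits in a library labelled MEF. In the macrophage list written before its values were examined, 19 of 26 genes (73.1%, exact interval 52.2 to 88.4) held a summit, against 0 of 20 lymphocyte (upper limit 16.8%), 0 of 15 neutrophil and mast cell, 0 of 15 germ cell (upper limit 21.8% for each) and 1 of 15 hepatocyte genes (Apoa2; upper limit 31.9%). The 19 macrophage genes included the scavenger receptor gene Msr1 at a fold of 8.16, the transcription factor gene Spi1 at 2.99, and the complement genes C1qb at 3.02 and C1qa at 2.13, with up to 2657.01 background reads in C1qb. Cx3cr1 and Trem2 had no summit. In the macrophage and blood list fixed before the data were examined, 3 of 10 genes held a summit (30%, 73.2nd percentile), and Csf1r and Adgre1 had none. Reads shared between Lyz2 and its neighbour Lyz1 alone are argued against by 16 of 35 other genes of both macrophage lists with backgrounds above the median, and a library of macrophages alone by 9 of 34 fibroblast genes in the top 10% of backgrounds, among them Postn, Sparc and Lox. RNA from macrophages in the culture may account for the pattern, although Ctsb is also expressed by fibroblasts, and the labels name no sort that would have removed such cells. Induction of these genes in the fibroblasts was not tested, and the share of such cells was not estimated.

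Regions of the same gene resembled each other in enrichment. Over 16915 regions of 3580 genes with measured backgrounds, the intraclass correlation of log2 IP over background within genes was 0.40 (0.402529), against −0.0107 to 0.0258 in 100 shuffles between genes at like background. This is consistent with enrichment of whole transcripts rather than of single sites, which a precipitation of unfragmented RNA could give, and methylation that differs by gene would give the same value. In 61 genes with 5 or more regions, every region's strongest summit was at the genome-wide background, but regions of a gene share its depth, so this count decides nothing. A difference in amplification between the libraries cannot be told apart from enrichment of these transcripts, because there was 1 library of each kind.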
